A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

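RNA crosslinked to HTB-tagged Mip6 was sequenced from yeast kept at 30 °C or moved to 39 °C for 20 min. Per the labels' protocols, cells were labelled with 4-thiouracil and irradiated at 365 nm for 15 min. Mip6 was then purified on nickel and streptavidin beads, with RNase treatment, before adaptors were ligated, RNA was reverse transcribed and cDNA was amplified by PCR. The labels split each temperature into a minus-strand and a plus-strand sample, which gave 4 files. Per the submitters' processing notes, Bowtie 1.1.1 and HTSeq were used with the builds sacCer3 and R64. The mismatch filter, the strand setting of the counting, any removal of duplicates and the annotation are not given in the sources used here.

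The deposited count files hold whole-number read counts per feature, not normalized, followed by 5 HTSeq summary rows. These summary rows were left out of the library totals. Reads in no feature made up 22.3% of all counted reads in the 30 °C minus-strand sample, 23.8% in the 30 °C plus-strand sample, 22.4% in the 39 °C minus-strand sample and 24.7% in the 39 °C plus-strand sample. Reads ambiguous between features made up 9.94%, 3.92%, 13.3% and 4.51% in the same order. Features with reads of both strands in each file show that the counts are not limited to the file's strand, so an antisense transcript adds to a feature's count.

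The series also has a table of the authors' own comparison, which was used only to describe their calls, for feature lengths and for the closing tests. The columns used of the authors' deposited table hold a log2 ratio, a probability and a signed ranking, which are scores of the authors' comparison and not p-values, the feature length and a call of up, down or flat. Another 2 columns hold values per library under names that match no label, and they were not used. The tool that made the table is not given in the sources used here. Over 757 features with at least 20% of reads on the other strand, the log2 ratio in the authors' deposited table had a Pearson correlation of 0.983 with the own-strand ratio and of 0.631 with the summed ratio, across features. The features called up or down are those with a probability above 0.9 in the authors' deposited table.

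The files hold 7126 features, of which 6162 matched the RefSeq annotation of assembly R64 by locus tag or symbol and 964 did not. Names and coordinates come from that annotation, which is of the same build as the processing notes name. The strand of a feature was read from its systematic name. Both strand files of a temperature were summed per feature to 1 library. CPM were taken over the reads in features, and the log2 ratio of 39 °C over 30 °C was computed after adding 0.5 to each count. Features with at least 20 reads over both libraries were tested for a ratio of at least 2-fold. With 1 library per temperature no test across libraries was run. The 95% interval of each ratio is the exact conditional binomial interval, and that of a share is Clopper-Pearson. The floor for a count of 0 is 3 counts. All of these treat reads as independent, and they cover counting error only and not the difference between cultures.

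A gene list's shift is the median log2 ratio of its measured members minus the median of all tested features. Its counting interval comes from 1000 Poisson redraws of the counts. Its percentile is taken among 10000 random lists of the same size with as many members in each of 10 classes of mean reads, as a description of these libraries. The 19 lists were written before the data were examined, and 1 member of the amino acid list did not match a feature. Genes were named by a rule fixed beforehand. It takes MIP6, PES4 and MEX67, the 12 features highest and the 12 lowest by the interval bound nearest to no change among those with at least 50 reads and 2-fold, and the 8 of highest CPM in each library. It also takes the 4 members of each list with most reads and, for the Msn2/4 and Hsf1 lists, the 4 members of highest and 2 of lowest ratio. Unmatched features were not named, and single values of some genes are not reported here. Other genes are marked as named after their values were seen.

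The calculation was tested on simulated counts drawn from the libraries' means, in which 6555 features reached at least 20 reads. Of the simulated genes, 50 of 50 set 4-fold higher, 50 of 50 set 3-fold higher, 49 of 50 set 4-fold lower and 50 of 50 set 3-fold lower passed the 2-fold rule. It was also passed by 10 of 6356 unchanged features. The intervals held the simulated ratio for 95.3% of features. A list shift set to 0.5 came out as 0.51, and 10 of 200 unshifted lists fell outside the middle 95% of random lists. The simulated counts were independent Poisson draws, without PCR copies or differences between cultures. These rates therefore check the calculation and are not error rates of the calls in the real libraries.

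Alternatives fixed before the data were examined were TMM factors, DESeq2 size factors, totals of each strand, totals without the 10 features of most reads, other read minimums, fold thresholds and added counts, own-strand reads alone, protein-coding genes alone, genes of 1 strand, matching on length, pooled list ratios, reads per kilobase and a stricter probability. Thinning the 30 °C library to the depth of the 39 °C library, other thresholds for the within-strand counts, and lists without RPP1 or without linker and variant histones were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with R 4.3.3, edgeR 4.0.16 for the TMM factors and DESeq2 1.42.0 for its size factors.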

Results

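Mip6 is a yeast RNA-binding protein, and the study it comes from addresses its contact with the mRNA export receptor Mex67 and the mRNAs of stress genes controlled by the transcription factors Msn2 and Msn4. RNA bound by Mip6 was mapped by PAR-CLIP, in which cells take up 4-thiouracil and ultraviolet light crosslinks the labelled RNA to protein. The labels name 4 samples of Saccharomyces cerevisiae carrying an HTB-tagged Mip6, a minus-strand and a plus-strand sample at 30 °C and the same pair after 20 min at 39 °C. The cells had 4-thiouracil for 45 min at 30 °C, or for 25 min at 30 °C and 20 min at 39 °C, before 15 min of light at 365 nm. The strands of a temperature are parts of 1 library and not replicates, so there was 1 library per temperature, no test between temperatures was possible and no p-value is given.

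Reads assigned to features numbered 5770372 in the 30 °C minus-strand sample and 5886856 in the 30 °C plus-strand sample. The corresponding totals were 3482333 and 3468207 at 39 °C. Summed over strands, the 30 °C library held 11657228 reads and the 39 °C library 6950540. A tested feature had a median of 1317 reads at 30 °C and 785 at 39 °C. A count of 0 allows up to 0.257 CPM, the reads of a feature scaled to the library total, at 30 °C and 0.432 CPM at 39 °C. No input RNA or untagged control was among the samples, so a read level reflects the mRNA level as well as crosslinking. The 95% intervals of single ratios and of read shares are exact binomial intervals, and those of list shifts come from Poisson redraws. They treat reads as independent and cover counting error only, not the difference between cultures. Reads copied by PCR are not independent molecules, and whether duplicates were removed is not given. The intervals may therefore be too narrow even for counting error.

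The most heavily read mRNAs at 30 °C coded for chaperones, glycolytic enzymes, a zinc transporter and translation proteins. HSP82, the inducible Hsp90 chaperone (YPL240C, chromosome XVI, 96496 to 98625, build R64), led with 2816.7 CPM. It was followed by TPI1, triose phosphate isomerase, with 2746.2 CPM and HSP104, a disaggregase, with 2480.0 CPM. ZRT1, a high-affinity zinc transporter, had 2324.2 CPM, HSC82, the constitutive Hsp90, 2130.4 CPM and FBA1, aldolase, 2104.2 CPM. TMA19 had 1987.8 CPM and RPS12, a ribosomal protein gene, 1903.2 CPM. At 39 °C the 6 highest were all chaperone genes. HSP82 reached 8054.2 CPM, HSP104 4989.5 CPM, HSC82 4375.8 CPM, the small heat shock protein gene HSP26 2717.1 CPM, the Hsp70 gene SSA1 2670.0 CPM and the mitochondrial chaperone gene HSP78 2389.9 CPM. TPI1 with 2282.4 CPM and ZRT1 with 2269.6 CPM came next. These levels are per feature, leave out reads ambiguous between features and were not divided by length.

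By gene list, the genes of the cytosolic ribosomal protein list held 5.19% of reads at 30 °C (95% Clopper-Pearson interval 5.18 to 5.2) and 3.28% at 39 °C (3.27 to 3.29). Chaperone genes of the heat shock factor Hsf1 went the other way, from 2.14% (2.13 to 2.15) to 4.71% (4.7 to 4.73). The share of the Msn2/4 stress targets was 2.08% (2.07 to 2.09) at 30 °C and 2.86% (2.84 to 2.87) at 39 °C. Without the 4 genes also on the Hsf1 list it was 1.68% (1.67 to 1.69) and 1.8% (1.79 to 1.81). Glycolysis and fermentation genes held 1.71% and 1.88%, and ribosome biogenesis genes 2.96% and 2.38%. Meiosis and sporulation genes held 0.329% and 0.395%. Per kilobase of feature the ribosomal protein share was 10.9% at 30 °C and 7.62% at 39 °C, and the Hsf1 share was 1.3% and 3.1%. None of the 28 mitochondrially encoded features in the count files had a read. Whether the mitochondrial chromosome was part of the mapping and counting is not given in the sources used here. The lack of reads therefore does not show that Mip6 makes no contact with mitochondrial RNA.

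The first comparison asked which RNAs differed in Mip6 PAR-CLIP reads after heat shock, which reflect the mRNA level as well as crosslinking. The largest ratio belonged to HSP30, a plasma membrane heat shock protein gene (YCR021C, chromosome III, 156109 to 157107), with 70.2 CPM at 30 °C and 1776.4 CPM at 39 °C, a log2 ratio of 4.66 (95% interval 4.56 to 4.77). BTN2, which codes for a protein sorting misfolded proteins, had 90.2 and 1116.5 CPM, a log2 ratio of 3.63 (3.54 to 3.72). The lowest ratio was that of HO, the mating-type switching endonuclease gene (YDL227C, chromosome IV, 46271 to 48031), with 195.4 CPM at 30 °C and 20.1 CPM at 39 °C, a log2 ratio of -3.27 (-3.53 to -3.03). Of 6554 features with at least 20 reads over both libraries, 253 were at least 2-fold higher at 39 °C, 140 were at least 2-fold lower, and 6161 lay within 2-fold. Protein-coding genes made up 204 of the higher and 105 of the lower features. With reads taken as independent, the counting interval excluded no change for 251 of the higher and 134 of the lower features. Log2 ratios had a median of 0.014 and quartiles of -0.29 and 0.31, and the Spearman correlation of CPM between the libraries was 0.938 across features, which are not independent replicates.

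The 12 features that ranked highest by the interval bound nearest to no change included, after HSP30 and BTN2, the Hsp70 gene SSA3 with a log2 ratio of 2.79 (2.72 to 2.87) and HSP26 with 2.21 (2.17 to 2.25). PUT1, proline oxidase, had a log2 ratio of 2.09 (1.94 to 2.24), CRC1, a mitochondrial carnitine carrier, 2.2 (1.96 to 2.46), and the short gene YER053C-A 2.07 (1.95 to 2.18). A pair of sporulation genes, SPR28 with 2.14 (1.93 to 2.36) and SPO74 with 2.1 (1.84 to 2.37), was among them, as was PES4. The 2 others owed most of their reads at 39 °C to the strand opposite the gene. YOR268C had a summed log2 ratio of 3.24, but 94.4% of its reads at 39 °C were on the other strand and its own-strand log2 ratio was 1.42 (0.47 to 2.44) from 16 and 25 reads. NIS1 had a summed log2 ratio of 2.25 with 91.9% of reads at 39 °C on the other strand, and an own-strand log2 ratio of -0.07 (-0.34 to 0.19).

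Among the 12 lowest, cell-cycle and DNA replication genes stood beside HO. MCD1, a cohesin subunit gene, had a log2 ratio of -1.81 (-1.95 to -1.68), RNR1, the large subunit of ribonucleotide reductase, -1.61 (-1.71 to -1.5), and the B-type cyclin gene CLB1 -1.44 (-1.54 to -1.34). FAR1, whose product arrests the cell cycle on pheromone, had -1.41 (-1.5 to -1.32). INA1 with -1.7, PRY1 with -1.65, ARG4 of arginine synthesis with -1.42 and ATP1, a subunit of the mitochondrial ATP synthase, with -1.41 were also among them. CCW22, which the annotation calls a pseudogene, had -1.95. The other 2 features had no entry in the RefSeq annotation and are not named.

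**Figure D1:**
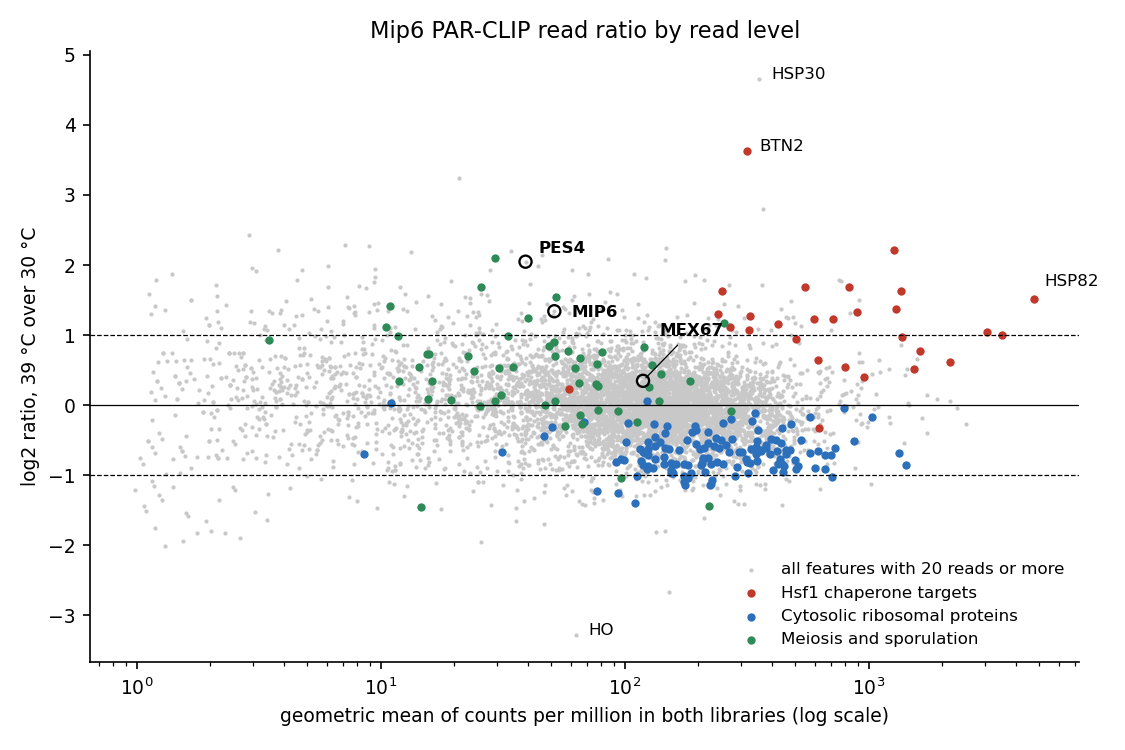
Log2 ratio of reads, 39 °C over 30 °C, against the geometric mean of CPM in both libraries on a log axis, 1 point per feature with at least 20 reads; dashed lines mark 2-fold, coloured points are 3 gene lists and black rings the 3 proteins of the study. HSP30 at 4.66 and HO at -3.27 are the extremes, most Hsf1 targets lie above 0 and most ribosomal protein genes lie below it.

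For the proteins of the study, MIP6 itself (YHR015W, chromosome VIII, 134554 to 136533) had 32.3 CPM at 30 °C and 81.7 CPM at 39 °C, a log2 ratio of 1.34 (1.15 to 1.53) from 376 and 568 reads. PES4, which codes for a related RNA-binding protein (YFR023W, chromosome VI, 199874 to 201709), had 19.2 and 79.6 CPM, a log2 ratio of 2.05 (1.82 to 2.28). With reads of the gene's own strand alone the log2 ratios were 1.55 for MIP6 and 2.29 for PES4. MEX67 (YPL169C, chromosome XVI, 229039 to 230838) had 105.2 and 133.8 CPM, a log2 ratio of 0.35 (0.22 to 0.47). All 3 are in the list of nuclear mRNA export and RNA-binding adaptors, whose 35 genes were otherwise within 2-fold. That list had a median shift of -0.04 against all tested features, at percentile 49.41 of random lists of the same size matched on mean reads, of which 10000 were drawn. As a pooled ratio its shift was -0.14. GBP2 with -0.15, YRA1 with -0.54, SEM1 with -0.32 and MLP1 with 0.09 were its members with most reads.

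The next comparison asked how gene groups differed, with 19 lists fixed before the data were examined. The Hsf1 chaperone targets were higher at 39 °C as a group. Of the 30 genes 28 had counted reads, and their median shift over all tested features was 1.13 (counting interval 1.09 to 1.18), above all of the 10000 random lists. At least 2-fold higher were 18, none was 2-fold lower and 10 lay within 2-fold. BTN2 led, followed by HSP26, the nucleotide exchange factor gene FES1 with a log2 ratio of 1.69 (1.64 to 1.73) and the Hsp90 co-chaperone gene CPR6 with 1.68 (1.62 to 1.74). HSP82 had 1.52 (1.5 to 1.54), HSC82 1.04 (1.01 to 1.06), HSP104 1.01 (0.99 to 1.03) and SSA1 0.61 (0.58 to 0.64). The lowest members were the mitochondrial Hsp70 genes SSC1 with -0.33 (-0.38 to -0.27) and ECM10 with 0.23 (0.05 to 0.4). The metallothionein genes CUP1-1 and CUP1-2, also on the list, are listed with 0 reads in the count files. They lie inside the noncoding features RUF5-1 and RUF5-2 on the opposite strand, so their reads may have been set aside as ambiguous. Their 0 does not show that they were unread, as the authors' deposited table holds ratios for both.

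The Msn2/4 stress targets, the genes named in the study's title, went both ways. All 60 had reads, and their median shift was 0.08 (0.04 to 0.17), at percentile 97.21 of matched random lists. As a pooled ratio of all reads on the list the shift was 0.44. At 39 °C 8 were at least 2-fold higher, 3 were 2-fold lower and 49 lay within 2-fold. SSA3, HSP26, HSP42 with 1.63 (1.55 to 1.72) and HSP78 with 1.63 (1.59 to 1.66) were the highest. Of the 8 higher genes, HSP104, HSP26, HSP42 and HSP78 are also on the Hsf1 list. Without these 4 genes the shift of the Msn2/4 list was 0.05, with 4 genes higher and 3 lower. Besides SSA3, the rest of the higher genes, named after their values were seen, were MOH1 with 1.31, TMA10 with 1.04 and GPX1 with 1.01. The 3 lower genes all act in glycogen metabolism, namely glycogen synthase GSY1 with -1.41 (-1.6 to -1.22), glycogen phosphorylase GPH1 with -1.28 (-1.38 to -1.19) and GDB1, the debranching enzyme, with -1.09, the last named after its value was seen. HOR7 with -0.18 and HSP31 with 0.66 were among the members with most reads. The percentile of this list ran from 76.3 with plus-strand genes alone to 99.3 with the 30 °C library thinned, so its place against random lists depended on the setting.

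The same 3 glycogen genes were the only 2-fold lower members among 19 trehalose and glycogen genes, of which none was 2-fold higher. That list's shift was -0.11, at percentile 37.04. TSL1, a subunit of trehalose synthase, had a log2 ratio of 0.48 (0.43 to 0.53), while PGM2 had -0.27, UGP1 -0.51 and the phosphatase gene GLC7 -0.1. The shift was 0.15 with minus-strand genes alone, and the list lay at percentile 1.9 when random lists were matched on length.

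Genes of protein synthesis were lower at 39 °C. The list of cytosolic ribosomal protein genes held 138 genes, 1 of which, RPP1, codes for a subunit of RNase P and not for a ribosomal protein, and had a median shift of -0.7 (-0.72 to -0.68), below all matched random lists (percentile 0.0). Of them 13 were at least 2-fold lower, none was 2-fold higher and 125 lay within 2-fold, with 2 above the median of all tested features. Without RPP1 the shift was -0.7 over 137 genes. RPS12 had a log2 ratio of -0.85 (-0.88 to -0.81), RPS31 -0.68, RPL43B -0.51 and RPL3 -0.17. The 112 ribosome biogenesis genes had a shift of -0.35 (-0.36 to -0.31) at percentile 0.0 with all members within 2-fold, such as the RNA helicase gene DBP2 with -0.61, NOG2 with -0.53, DIP2 with -0.38 and UTP20 with 0.3. Translation initiation and elongation factors had a shift of -0.37 over 38 of 39 genes at percentile 0.05. TMA19 with -0.4 and YEF3 with -0.53 were lower, while the near-identical elongation factor genes TEF1 and TEF2, between which reads are uncertain, differed little, with 1461.9 CPM at 30 °C and 1458.9 CPM at 39 °C for TEF1 and 1435.6 and 1467.2 CPM for TEF2. The 69 mitochondrial ribosomal protein genes had a shift of -0.3 (-0.34 to -0.26) at percentile 0.0, with RSM10 at 0.01, MRPS35 at -0.23, MRPL6 at -0.17 and MRPL10 at -0.13.

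Nuclear genes of the respiratory chain and ATP synthase had a shift of -0.51 (-0.54 to -0.46) at percentile 0.0, with 4 of 38 genes 2-fold lower and none 2-fold higher. These were ATP1 and, named after their values were seen, ATP16 with -1.15, COX4 with -1.14 and COX8 with -1.04. ATP2 had -0.93 (-1.0 to -0.85), ATP4 -0.5, COX13 -0.23 and QCR8 -0.06. The 11 histone genes listed had a shift of -0.44 (-0.51 to -0.38) at percentile 0.96 with none past 2-fold. They include the linker histone gene HHO1 and the variant histone genes HTZ1 and CSE4, and without these 3 the shift of the 8 core histone genes was -0.43 at percentile 3.33, inside the middle 95% of random lists. HTA2 had -0.79, HHF1 -0.61, HHF2 -0.4 and HHT1 -0.09. The histone list lay at percentile 20.83 with plus-strand genes alone and at 5.54 when random lists were matched on length.

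Amino acid biosynthesis genes had a shift of -0.22 (-0.27 to -0.19) over 69 genes at percentile 0.27, with 3 at least 2-fold higher and 3 lower. The glutamine synthetase gene GLN1 had 1.07 (1.02 to 1.12), and MET6 with 1.26 and SHM2 with 1.12, named after their values were seen, were the other higher members. The lower members included ARG4 and, also named afterwards, HOM2 with -1.12. ILV5 had -0.76 and ASN1 -0.19. With plus-strand genes alone the list lay at percentile 15.35.

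Meiosis and sporulation genes, many of which are lowly expressed in growing cells, were the other list above the random lists. The 53 genes had a median shift of 0.48 (0.36 to 0.53), above all of the 10000 random lists, with 7 at least 2-fold higher, 3 lower and 43 within 2-fold. As a pooled ratio the shift was 0.25. Besides SPO74, the higher members were IME1, the master regulator of meiosis, with a log2 ratio of 1.69, DIT1 with 1.54, LOH1 with 1.42, MEI4 with 1.24, ZIP2 with 1.17 and DIT2 with 1.11, most of them named after their values were seen. DIT2 had an own-strand log2 ratio of 0.46, under 2-fold. The lower members were SPS4 with -1.46, CLB1 and the cyclin gene CLB5 with -1.04. CLB1 had 363.0 CPM at 30 °C and is also taken as a cell-cycle gene below, so it does not stand for sporulation alone. ADY4 had 0.35 (0.25 to 0.45). Many reads of this group lay on the strand opposite the gene. That share was 95.3% at 30 °C for SPO77, which had a log2 ratio of -0.08, and 89.1% for ZIP2. The median other-strand share was 45.8% at 30 °C over the list and 6.0% over all reading frames.

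The remaining lists lay inside the middle 95% of random lists. Glycolysis and fermentation genes had a shift of 0.13 (0.09 to 0.15) at percentile 96.86 with all 20 within 2-fold, among them TDH3 with 0.09, ENO2 with 0.14, FBA1 with 0.06 and TPI1 with -0.27. From own-strand reads alone this list lay at percentile 98.53. Endoplasmic reticulum folding and translocation genes had a shift of -0.15 at percentile 4.81 and of 0.13 as a pooled ratio, and held the Hsp70 gene KAR2 with 1.5 (1.45 to 1.54) and the oxidase gene ERO1 with 1.26 (1.2 to 1.33). HAC1 with 0.22 and SEC63 with -0.12 were within 2-fold. Proteasome genes had a shift of -0.16 at percentile 28.29, with RPN8 at -0.17, RPT5 at -0.05, PUP2 at -0.24 and RPT1 at -0.25. The single 2-fold higher member of that list, named afterwards, was RPN4, the transcription factor of proteasome genes, with 1.25. Ergosterol genes had a shift of -0.09 at percentile 36.15, with ERG20 at -0.87, ERG1 at -0.23, ERG3 at 0.37 and IDI1 at -0.07. Cell wall and plasma membrane genes had a shift of 0.05 at percentile 81.97 and of -0.13 as a pooled ratio, with PMA1 at -0.01, ZEO1 at -0.26, FKS1 at 0.14 and GAS1 at -0.24. Its members past 2-fold, named afterwards, were DAN1 with 2.28 and PST1 with 1.25 on the higher side, and SCW4 with -1.29 and EXG1 with -1.05 on the lower side. The own-strand log2 ratio of DAN1 was 0.26. The 8 mitochondrially encoded genes had no reads, and the Ty list matched no feature, so neither list could be compared.

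**Figure D2:**
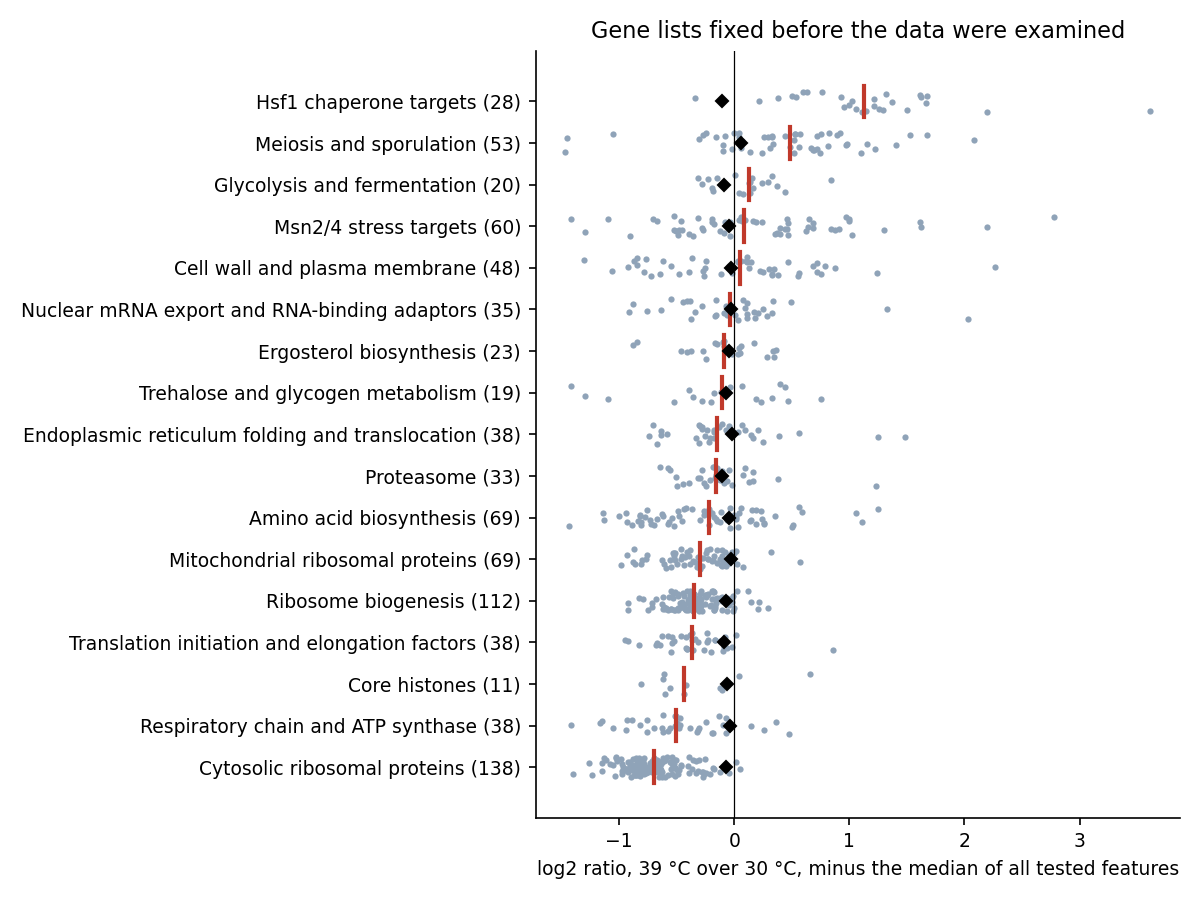
Log2 ratio, 39 °C over 30 °C, minus the median of all tested features, for the members of 17 gene lists with the number measured in brackets. Each point is a gene, the red bar is the list's median and the black diamond the median of 10000 matched random lists; the Hsf1 list at 1.13 and the cytosolic ribosomal proteins at -0.7 lie farthest apart.

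Within the strand files the picture was examined separately, since a group resting on genes of 1 strand would show it. Among 3100 minus-strand features in the minus-strand samples, 146 were at least 2-fold higher at 39 °C and 88 lower. Among 3161 plus-strand features in the plus-strand samples, 128 were higher and 82 lower. The Hsf1 list had a shift of 1.03 over 16 minus-strand genes and 1.27 over 12 plus-strand genes. The ribosomal protein list had -0.7 over 63 and -0.64 over 75 genes. The Msn2/4 list had 0.31 over 26 minus-strand genes and 0.0 over 34 plus-strand genes, a difference that was not tested. From summed reads the shift of the same genes was 0.14 for the minus strand and 0.0 for the plus strand. Reads on the strand opposite a reading frame made up 8.62% of reading-frame reads at 30 °C and 11.4% at 39 °C. Of 250 higher features with a known strand, 191 were also at least 2-fold higher from own-strand reads, and 12 had an own-strand ratio below no change. Of 138 lower features, 111 were also 2-fold lower and 11 had an own-strand ratio above no change.

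**Figure D3:**
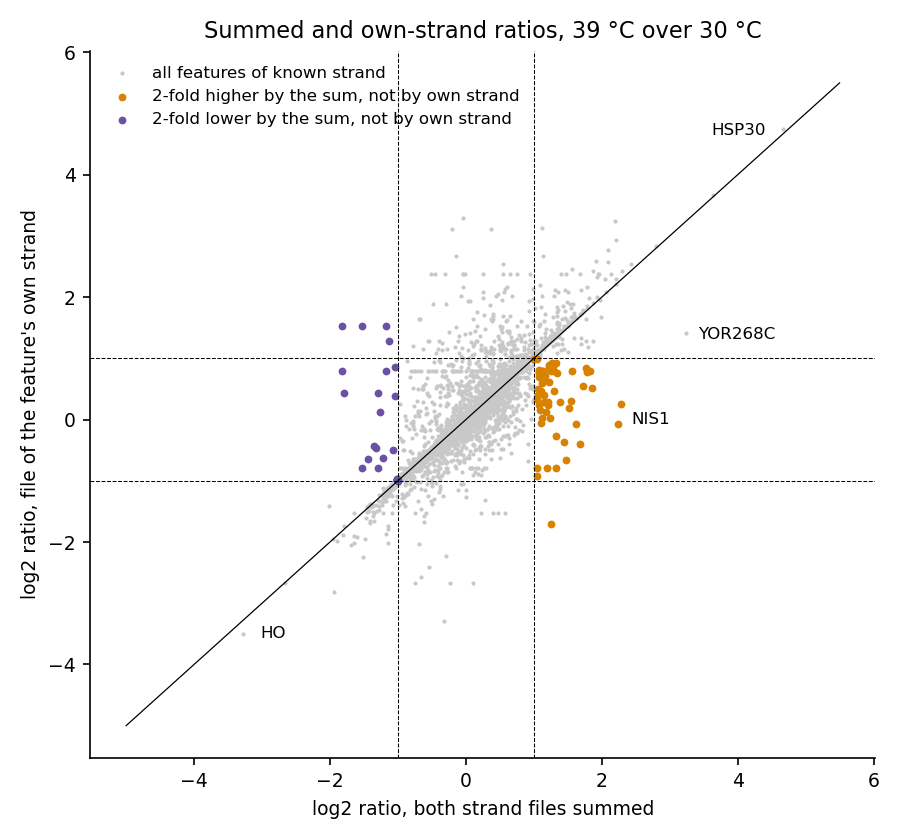
Log2 ratio, 39 °C over 30 °C, from the file of the feature's own strand against that from both strand files summed, 1 point per feature; dashed lines mark 2-fold and the solid line equality. Orange points are 2-fold higher only by the sum, such as NIS1 with 2.25 by the sum and -0.07 by its own strand.

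The last comparison set these ratios beside the authors' own calls. The authors' deposited table called 211 features up, 354 down and 6561 flat. It holds a ratio for 6918 features, so those called flat include features without a ratio. The header does not give the direction of its log2 ratio, which was read here from the match to the count files. Over 5609 features with at least 200 own-strand reads, its log2 ratio, turned to 39 °C over 30 °C, had a Pearson correlation of 0.995 with the own-strand ratio, across features. Of 30 Hsf1 targets, 25 were up and none was down in the authors' deposited table, and 84 of the 137 cytosolic ribosomal protein genes without RPP1 were down and none was up. Of the 60 Msn2/4 targets, the authors' deposited table called 14 up, 4 down and 42 flat. In the authors' deposited table the genes down included 11 of 38 respiratory genes, 8 of 69 mitochondrial ribosomal protein genes and 6 of 112 ribosome biogenesis genes. Of 53 meiosis genes, the authors' deposited table called 1 up and 3 down.

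Of the features called up in the authors' deposited table, 117 were also at least 2-fold higher here, and 208 of the 209 tested here lay above the median. Of those called down in the authors' deposited table, 98 were at least 2-fold lower, and 350 of 353 lay below the median. The direction of its log2 ratio was read from these count files, so this agreement in direction was set beforehand and is no independent support. The calls in the authors' deposited table rest on a probability above 0.9 and not on 2-fold, with a smallest absolute log2 ratio of 0.61 among them. The numbers of shared features therefore also reflect unlike thresholds. Another 135 features at least 2-fold higher here were flat in the authors' deposited table, with a median of 234 reads against 1944 for those also called up. Read number was not the only difference, as the ratio in the authors' deposited table follows own-strand reads. Of 59 features 2-fold higher by summed but not by own-strand reads, 58 were under 2-fold in the authors' deposited table. MIP6 with a log2 ratio of 1.46 and PES4 with 2.32 were flat in the authors' deposited table, with probabilities of 0.864 and 0.898 against its threshold of 0.9. HSP30 with 4.78, BTN2 with 3.68 and HSP82 with 1.55 were up in the authors' deposited table, and HO was down with -3.55. CUP1-1 and CUP1-2 were up in the authors' deposited table, with 2.02 and 2.04.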

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

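The tests on the RUF5 features, and those on other-strand reads and weakly counted features as a source of the meiosis shift, were chosen after the result was seen.

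Reads outside the features compared were present in all 4 samples, and no control sample was there to set them against. Reads in no feature made up 22.3% and 23.8% in the minus-strand and plus-strand samples at 30 °C, and 22.4% and 24.7% at 39 °C. Reads ambiguous between overlapping features made up 9.94% of the minus-strand and 3.92% of the plus-strand sample at 30 °C, and 13.3% and 4.51% at 39 °C.

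Meiosis and sporulation genes were higher at 39 °C as a list, with a shift of 0.48. Reads from the other strand were tested first, since the list held a median of 45.8% of them at 30 °C, and with own-strand reads alone the shift was 0.55 and above all matched random lists. The median log2 ratio did run from 0.24 in the least read eighth of protein-coding genes to -0.12 in the most read, but the least read eighth lay 0.22 above the median of all tested features, below the counting interval of the list's shift (0.36 to 0.53), which argues against a general rise of weakly counted features as the whole cause. A flat background, estimated from other-strand reads at 2.09 CPM per kilobase at 30 °C and 3.0 at 39 °C, scaled to own-strand totals, left a shift of 0.64 once subtracted. A change in mRNA level or in Mip6 binding with temperature stays open as a hypothesis that may account for it, and no mRNA measurement was used to separate them.

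RUF5-1 and RUF5-2, noncoding features on the plus strand of chromosome VIII (212409 to 213118 and 214407 to 215116), were higher at 39 °C in the count files, with summed log2 ratios of 1.78 and 1.77. The copper metallothionein genes CUP1-1 and CUP1-2 lie inside them on the minus strand and have 0 reads in the count files. A read within CUP1 also overlaps RUF5 and may have been set aside as ambiguous. That would leave reads in the rest of RUF5 to be counted. Minus-strand reads of RUF5-1 numbered 3581 at 30 °C and 8586 at 39 °C, against 1175 and 1161 on its own strand, whose log2 ratios were 0.75 for RUF5-1 and 0.81 for RUF5-2. In the authors' deposited table, which has values for both, the higher log2 ratio of the RUF5 features was 0.14 and the lower of the CUP1 genes 2.02. These values are consistent with CUP1 reads being counted for RUF5 where strand was not used, but the RUF5 values in the authors' deposited table also lie below the own-strand ratios of the count files for a cause not tested, and no biological explanation was tested.

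In total 59 features were at least 2-fold higher by summed reads but not by own-strand reads, with a median log2 ratio of 1.22 by the sum and 0.5 by the own strand. Of 15 with a convergent neighbour, 2 had one that was 2-fold higher by own-strand reads, which is 13.3% against 3.1% of other reading frames, and with so few this source cannot be told apart from others. An earlier test over all reading frames had given Spearman correlations of the other-strand ratio of 0.12 with the convergent and 0.09 with the divergent neighbour. Whether temperature set off antisense transcription was not tested.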

How the results depend on the processing

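Thinning of the 30 °C library, the alternatives of the within-strand counts and the lists without RPP1 or without linker and variant histones were chosen after the data were seen. No paired analysis was possible because there was 1 library per temperature, and for the same reason no library could be left out. Reads per kilobase of thymidine were not run, as no genome was used. For 97 named genes, 760 of 776 recomputed log2 ratios kept their sign, and for 14 further lists 235 of 239 shifts did, with no call reversed among the lists. Most settings behind the 776 ratios change only the library totals or the added counts. These move the ratio of a well-read gene little, so few signs could change there. Part of these 239 shifts could not change. A new library total for all features, random lists matched on length or the removal of genes shared by other lists leaves a shift as it was. NIS1 reversed, with a log2 ratio of -0.07 from own-strand reads, a setting that leaves out its other-strand reads. Features at least 2-fold lower numbered 214 with no read minimum. A 1.5-fold threshold gave 733 higher and 689 lower, and a 3-fold threshold 57 and 17. Within strands, a minimum of 100 reads left 97 minus-strand and 82 plus-strand features higher. A 1.5-fold threshold gave 356 higher and 409 lower on the minus strand and 360 and 357 on the plus strand, and a 3-fold threshold 38 and 12, and 32 and 13. These follow from the thresholds themselves. For the other moved values the cause was not tested. Lists above the middle 95% of random lists numbered 4 with own-strand reads, which added Msn2/4 and glycolysis. The ribosomal protein shift was then -0.67. The Hsf1 shift was 1.01 with minus-strand genes, 1.23 with plus-strand genes and 1.08 without the genes shared with Msn2/4. The Msn2/4 shift was 0.0 with plus-strand genes and 0.44 as a pooled ratio. Shares of reads moved with the file used and with division by length. For Msn2/4 targets they were 2.38% at 30 °C and 3.14% at 39 °C per kilobase, 1.56% and 2.21% in the minus-strand file and 2.59% and 3.5% in the plus-strand file. The Hsf1 shares were 1.3% and 3.1%, 2.7% and 5.54%, and 1.59% and 3.88% in the same order. The ribosomal protein shares were 10.9% and 7.62%, 4.52% and 2.77%, and 5.85% and 3.79%. With a probability above 0.95 the authors' deposited table called 78 up and 68 down. Depth limited weakly read features, where a count of 0 allows up to 0.432 CPM at 39 °C.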

Other observations

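The gene lists of cell cycle, mating, protein folding and nitrogen use were written after the values of some members had been seen. Those members were left out of each of these tests, and for the unfolded protein response list the test too was chosen after related values were known.

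Cell-cycle genes were lower at 39 °C beyond those that had drawn attention. HO, MCD1, RNR1, PRY1 and POL30, with a log2 ratio of -1.46, had prompted a list of G1/S genes. Its 40 other members had a median shift of -0.27, at percentile 0.16 of matched random lists, with 6 at least 2-fold lower and 1 higher. From own-strand reads the shift was -0.5. SMC1 with -0.06 was among those with most reads. CLB1 and SWI5, with -1.42, prompted a list of G2/M and M/G1 genes, whose 33 other members had a shift of -0.46 at percentile 0.0, with 6 lower and none higher. The daughter-cell genes DSE1 with -1.2 and AMN1 with -1.13 were among the lower ones, and the myosin gene MYO1 had -0.23. One hypothesis is that mRNAs of periodic cell-cycle genes were less available to Mip6 after 20 min at 39 °C, which is consistent with both percentiles and cannot be separated from a change in binding here.

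Pheromone response and mating genes were prompted by MFA1 with -1.43, FAR1 with -1.41 and the receptor gene STE2, which had 1505.3 CPM at 30 °C and 691.3 CPM at 39 °C. The 29 other members measured had a shift of -0.17 at percentile 4.03, inside the middle 95% of random lists, so a lower level of the class was not borne out by summed reads. From own-strand reads the shift was -0.26, which was not set against random lists. STE6 had -0.83, STE4 -0.35 and GPA1 -0.36. KAR2 and ERO1 prompted a list of unfolded protein response chaperones expected to be higher. The 19 others had a shift of -0.17 at percentile 7.66, and PDI1 had -0.29, CUE1 -0.17 and FPR2 -0.73, so KAR2 and ERO1 did not stand for the class.

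Genes repressed by good nitrogen sources were prompted by PUT1 and DAL1, with 1.77. The 26 other members measured had a shift of 0.32 at percentile 99.86, although none was 2-fold higher and 4 lay below the median. GDH2 had 0.36, PRB1 0.32 and APE1 0.04. A relief of nitrogen repression in the heat-shocked culture is a hypothesis that the percentile of 99.86 would allow, and no mRNA measurement was used to examine it.

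The classes of noncoding RNA come from the annotation, were looked at after the data were seen and were described whole, with no member left out and no prediction. Among them, 5 snRNA features had a median shift of 0.46 at percentile 97.58, with LSR1 at 0.47, SNR19 at 0.47 and SNR14 at 0.1. The 6 rRNA features measured include repeat copies of the same RNA, such as RDN5-1 and RDN5-6 with 0.61 each, between which reads are uncertain, so they are not separate members and no percentile is given. The 76 snoRNA features had a shift of -0.17 at percentile 0.49 with 4 of them 2-fold lower, although the 3 with most reads were not lower, with SNR86 at 0.27, SNR30 at 0.47 and SNR84 at 0.01.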
